A study of Hydra oligactis with 13 samples.

How the data were processed

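The data are 13 one-colour Agilent arrays of Hydra oligactis polyps (4 tumour-bearing, 3 in oogenesis, 6 asexual), each with 44957 spots, of which 43540 are not controls. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on a cartridge and by precipitation, and about 400 ng was labelled with Cy3. Scans were read with Agilent Feature Extraction 10.7.3, per the submitters' processing notes. Per the file headers, the deposited spot values are fluorescence intensities on a linear scale: the processed signal is background-subtracted and detrended, and the median signal is raw. Flags for background, saturation and outlier pixels are values of 0 or 1 in the same deposited files. The authors' deposited value table holds a ratio per spot. Set against the scanner values, each column equals the processed signal divided by that array's 75th percentile over unflagged spots that are not controls, with no centring of genes, and flagged spots are empty. Column medians lie between 0.104 and 0.146. Scale, centring and direction of that table are thus known. The files of 5 arrays (slides 1 and 2) hold fewer columns than those of the other 8 and lack mean and local background signals.

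Groups were taken from the sample labels. The headers show 4 slides and 2 scan days. Slide 1 held oogenesis 1, control 1, tumour 1 and tumour 2, slide 2 control 4, slide 3 controls 2 and 3 and oogenesis 2 and 3, and slide 4 controls 5 and 6 and tumours 3 and 4. Slides 1 and 2 were scanned on day 1 and slides 3 and 4 on day 2. Tumour arrays lay at positions 3 and 4 of their slides, control arrays at positions 1 and 2, oogenesis 1 at position 1 and oogenesis 2 and 3 at positions 3 and 4.

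Spots with an outlier flag (70 to 158 per array) were left out. The log2 processed signal was reduced by the array's 75th percentile, and spots of one probe were averaged. A probe was tested if it was well above background on at least 3 arrays, which held for 31144 probes. One more condition, at least 2 unflagged values per group, removed 1 probe and left 31143. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated and two-sided) with a mean for each of the 3 groups over all 13 arrays, 10 residual and 2.61 prior degrees of freedom, and contrasts between groups. P-values were adjusted by Benjamini and Hochberg over all tested probes, with a threshold of 0.05. Samples, design, alternatives and the rule for named items were fixed before the data were examined.

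Tumour 2 and tumour 4 differed by about the noise between spots, so their mean entered tumour means, SDs and bounds as 1 sample. The fit kept all 13 arrays as fixed beforehand, and log2 changes and p-values in the text come from it. A second fit with these 2 arrays averaged was added after the values were seen. Where a probe was not well above background on any array of a group, the change is given as a bound. The brighter group's mean is set against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Detection limits on this scale averaged -5.5 in control, -4.98 in tumour and -5.28 in oogenesis arrays.

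By the rule for files without gene names, named items are, per comparison, the 2 contigs with the largest rise and the 2 with the largest fall in fitted log2 change among probes with an adjusted p under 0.05 and groups that do not overlap, each contig being represented by its brightest probe. Fitted changes of probes below background on any array of a group have no order among themselves, and where only some arrays of the lower group were below background the change is also given with those arrays at their detection limits. No contig name had tested probes of more than 1 sequence, the 2 orientations of a contig counting as separate names. No gene names come with the files and no reference was used here, so 20 lists of genes fixed beforehand were not tested and gene names are not reported. Overlaps were compared with independent lists and with 20 splits of the controls, and the correlation and covariance of the changes also with 100 simulations that drew whole arrays of within-group deviations with replacement and random sign.

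The fit was tested on simulated data with the means and spreads of the 31143 probes and changes planted between tumour and control. Of 50 planted changes each, it recovered 0% at a log2 change of 0.5, 38% at 1, 80% at 2 and 98% at 4, with 3 false calls among 30943 unchanged probes. The simulated noise was normal and independent between probes and arrays, with 1 SD per probe in all groups. The real arrays hold close pairs, groups of unequal spread and spread shared between probes. These rates therefore describe the fit under simpler noise and are not error rates for these arrays. Alternatives covered normalization, the dim-probe filter, the variance model, array weights, slide and replicate number as blocks, single slides, pairs of groups, leaving out each array, and thresholds.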

Results

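Gene expression was measured in whole polyps of the freshwater cnidarian Hydra oligactis with one-colour Agilent arrays, on which Cy3-labelled RNA of one sample is hybridised to spotted oligonucleotides. The 13 samples fell into 3 groups of female polyps of the St. Petersburg strain. There were 4 samples of polyps carrying naturally occurring tumours, 3 samples of polyps in oogenesis and 6 samples of asexual control polyps. Oogenesis samples pooled stages 1 to 7 and came from animals moved from 18 to 10°C and left unfed, whereas the labels name only 18°C for the others. Temperature, feeding and oogenesis therefore varied together. The labels do not say whether samples of one group came from separate cultures, so the p-values below measure the spread between these samples, which may be partly technical.

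The array carried 42027 probes of 60 bases on 39861 contig names, and 8564 of its contigs had probes in both orientations. Every probe was described as unknown and 0 had a genome position, so the deposited files do not pair probes with genes and the few items named below are contigs. Between 62.2% and 76.9% of spots were well above background, from tumour 4 to control 1. The 75th percentile of the signal was 567 ± 117 in tumour, 757 ± 18.2 in oogenesis and 622 ± 104 in control arrays (SD, n = 4, 3 and 6). No spot was saturated. After filtering, 31143 probes were tested, and the number of arrays limits the precision.

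Arrays of different groups mostly differed more than arrays of one group. The scaled median absolute log2 difference between 2 arrays, taken over 15571 brighter probes, was 0.774 to 1.02 between control and oogenesis arrays and 0.52 to 0.841 between control and tumour arrays. Over all tested probes the correlation was 0.866 to 0.911 for the former pairs and 0.858 to 0.906 for the latter, so the measures do not rank these distances alike. Oogenesis arrays differed least among themselves, by 0.215 to 0.254. Control arrays differed from each other by 0.163 to 0.552. Controls 4 and 5, at 0.163, and controls 2 and 3, at 0.174, were close pairs, and no other pair of controls was below 0.318. All 6 controls were still counted as separate samples, so they may amount to fewer unrelated ones. Tumour 2 and tumour 4 differed by 0.097, although they lay on different slides scanned on different days, while the other tumour pairs reached 0.634. Tumour 1 was nearer to controls 3 and 2, at 0.52 and 0.553, than to any other tumour array, at 0.558 to 0.634, but by correlation over all tested probes it was nearer to the tumour arrays, at 0.938 to 0.946, than to these controls, at 0.898 and 0.892. The difference between tumour 2 and tumour 4 hardly recurred when measured with a second probe of the same sequence (r = 0.22 across 1446 such pairs of probes, against 0.87 to 1 for the other 77 pairs of arrays). These 2 tumour arrays therefore differed by about the noise between spots and were counted as 1 sample in every tumour mean and SD below (n = 3). Tests used all 13 arrays as designed, and the counts of changed and shared probes are also given with these 2 arrays averaged.

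**Figure D1:**
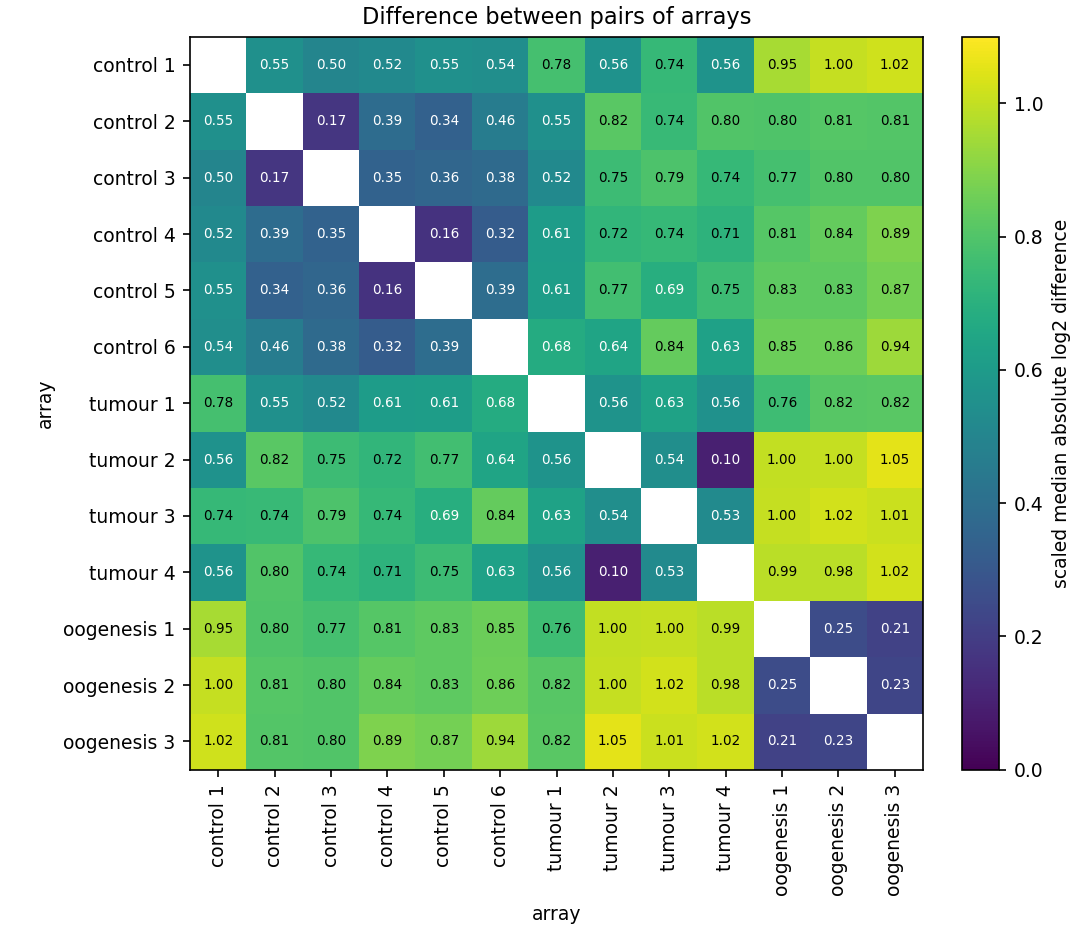
Scaled median absolute log2 difference between each pair of the 13 arrays, over the 15571 brighter probes; both axes list the arrays by group and the colour runs from 0 (equal) upwards. Oogenesis arrays form a tight block at 0.215 to 0.254, and tumour 2 and tumour 4 are the closest pair at 0.097.

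Tumour-bearing polyps were set against asexual control polyps to find the transcripts that differ between animals with and without tumours. In tumour-bearing polyps 4092 probes were higher and 5169 were lower than in control polyps, 29.7% of those tested (limma, adjusted p under 0.05). At least 2-fold changes made up 1910 of the higher and 3523 of the lower probes, and 1586 and 3233 with tumour 2 and tumour 4 averaged. The largest fitted falls were in transcripts that were abundant in control polyps and not well above background on any tumour array. Contig rcontig14001 stood at 6.62 ± 0.36 in control (n = 6) and -7.38 ± 0.44 in tumour polyps (n = 3) on the log2 scale relative to the 75th percentile, at least 3350-fold lower (log2 change -13.89, SE 0.24, adjusted p = 2.9e-12). Its probe reads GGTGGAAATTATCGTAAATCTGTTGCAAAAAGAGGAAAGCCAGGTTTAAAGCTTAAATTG. In oogenesis polyps it stood at 2.36 ± 0.16 (n = 3). Contig29135, with the probe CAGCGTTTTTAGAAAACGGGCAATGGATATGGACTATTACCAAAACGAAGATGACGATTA, stood at 5.12 ± 0.25 in control and -7.38 ± 0.49 in tumour polyps, at least 1190-fold lower (log2 change -12.39, SE 0.24, adjusted p = 3.4e-12).

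The largest fitted rises in tumour polyps were in contigs that oogenesis polyps did not carry above background and that only some control arrays showed. Contig18878 stood at 6.01 ± 0.73 in tumour and -3.5 ± 5.42 in control polyps. Its log2 change was 9.65 (SE 2.22, limma adjusted p = 0.0055, or 0.017 with tumours 2 and 4 averaged). Its control level was uneven, with 3.31 in control 4, 3.27 in control 5 and at most -4.43 in the other control arrays. Of those 4 arrays 1 had it well above background, and with the other 3 at their detection limits the log2 change was 8.36. The fitted change was 11.01 without control 4 or without control 5 and ranged from 7.32 to 13.05 over the alternatives. Its probe reads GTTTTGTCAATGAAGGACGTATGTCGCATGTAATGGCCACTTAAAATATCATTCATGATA. Contig29346, with the probe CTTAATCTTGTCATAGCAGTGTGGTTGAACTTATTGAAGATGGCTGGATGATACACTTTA, behaved alike, at 4.57 ± 0.64 in tumour and -4.95 ± 4.2 in control polyps (log2 change 9.37, SE 1.72, adjusted p = 0.0012). It stood at 0.35 and 0.54 in controls 4 and 5 and at most -7.06 in the other 4 controls, and with these at their detection limits the log2 change was 8.06. The fitted change was 10.43 without control 4, 10.47 without control 5 and 6.41 to 12.07 over the alternatives. Averaging tumours 2 and 4 gave a limma adjusted p of 0.004 for contig29346.

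With tumour 2 and tumour 4 as 1 sample, all tumour samples lay above or all below all control samples in 21.9% of the tested probes. Chance separates 2.38% if these samples are unrelated, and more if the close controls amount to fewer samples. With tumour 2 and tumour 4 averaged, 3118 probes were higher and 4357 lower, and 7344 calls were shared with the fit of 13 arrays. Averaging the close controls 2 and 3 and controls 4 and 5 as well left 5276 changed probes. Without controls 4 and 5, 6972 probes changed. Slides 1 and 4 held both tumour and control arrays, and with slide as a fixed block 6201 probes changed. Within slide 4, 2 tumour and 2 control arrays gave 2036 changed probes. Within slide 1, 2 tumour arrays against 1 control array gave 0 changed probes by limma with 1 residual degree of freedom and 2717 at an unadjusted p under 0.05. Of the 2036 probes called within slide 4, 77.4% had the same direction between tumour 1 and control 1 on slide 1, against 52.4% of all 31095 probes. Tumour arrays always took positions 3 and 4 of a slide and control arrays positions 1 and 2. Oogenesis 1, at position 1, differed from oogenesis 2 and 3, at positions 3 and 4, by 0.254 and 0.215, and these differed from each other by 0.229.

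**Figure D2:**
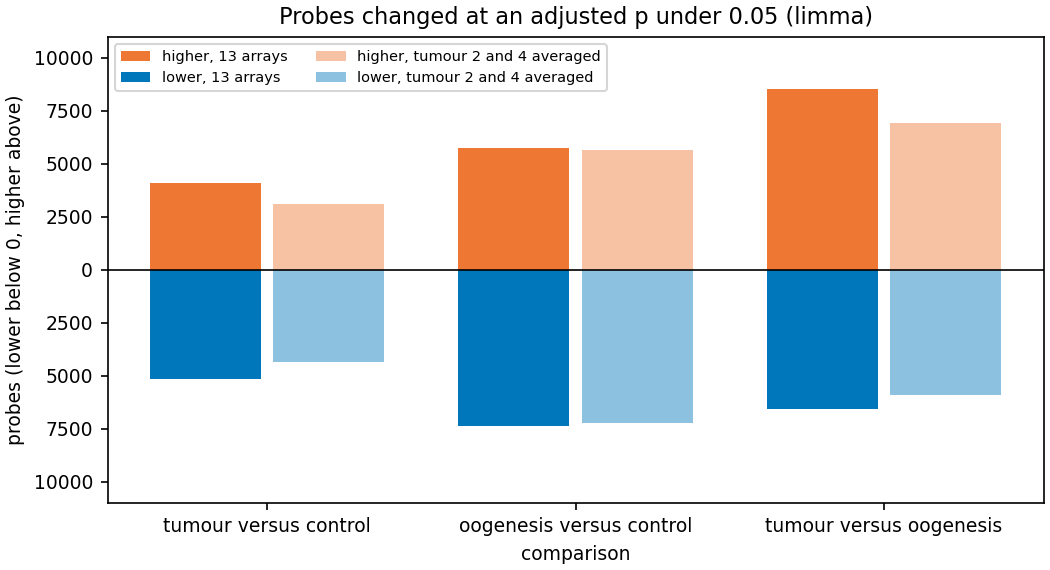
Number of probes higher (above 0) and lower (below 0) in each of the 3 comparisons at an adjusted p under 0.05, for 13 arrays (full colour) and with tumour 2 and tumour 4 averaged (pale). Tumour against control changes from 9261 to 7475 probes, and oogenesis against control from 13120 to 12911.

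Oogenesis polyps were set against asexual polyps as the comparison for egg formation. In oogenesis 5742 probes were higher and 7378 lower than in control polyps, 42.1% of those tested. Contig21032, with the probe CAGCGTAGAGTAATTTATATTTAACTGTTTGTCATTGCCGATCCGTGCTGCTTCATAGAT, stood at 7.98 ± 0.1 in oogenesis (n = 3) and -6.13 ± 1.05 in control polyps (n = 6), where it was well above background on 2 arrays (log2 change 14.11, SE 0.58, adjusted p = 4e-09). With the other 4 control arrays at their detection limits the log2 change was 13.24. In tumour polyps it stood at 3.29 ± 1.14 (n = 3), which was also above control (log2 change 9.32, or 8.56 at these limits, adjusted p = 3e-08). Contig24701, with the probe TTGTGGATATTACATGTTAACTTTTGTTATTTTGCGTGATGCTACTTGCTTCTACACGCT, stood at 5.31 ± 1.09 in oogenesis and -7.78 ± 0.34 in control polyps, where no array had it well above background, and was at least 1790-fold higher (log2 change 13.09, SE 0.41, adjusted p = 6.6e-10). It too was higher in tumour than in control polyps, at least 43.6-fold (adjusted p = 6.1e-09).

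By fitted change, the named falls in oogenesis were in contig08706 and contig08704, whose probes share 42 bases in a row and so measure overlapping sequence. Contig08706, with the probe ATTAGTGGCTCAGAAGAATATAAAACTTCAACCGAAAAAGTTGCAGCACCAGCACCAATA, stood at 2.29 ± 0.42 in control and -5.36 ± 2.18 in oogenesis polyps (log2 change -7.65, SE 0.73, adjusted p = 3.8e-06). Contig08704, with the probe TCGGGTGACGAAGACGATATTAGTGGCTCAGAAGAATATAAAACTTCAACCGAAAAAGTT, stood at 3.09 ± 0.44 and -4.47 ± 2.44 (log2 change -7.55, SE 0.78, adjusted p = 7.1e-06). Both were well above background on 1 of 3 oogenesis arrays. With the other 2 at their detection limits the log2 changes were -6.55 and -6.95, and over the alternatives the fitted ones ranged from -8.88 to -5.2 and from -8.93 to -5.57. Both were also lower in tumour than in control polyps (log2 change -2.08, limma adjusted p = 0.033, and -2.25, limma adjusted p = 0.031). These p-values lie near the threshold and count tumour 2 and tumour 4 separately, and none with these arrays averaged is given. Tumour 1 stood lowest, at -1.27 and -0.28, while the other tumour arrays stood at 0.57 or more.

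All oogenesis arrays lay above or all below all control arrays in 48.7% of the tested probes. Chance separates 2.38% if all samples are unrelated, and more if the close controls amount to fewer samples. The median log2 change of all tested probes was -0.235, so falls outnumbered rises relative to the 75th percentile. Scaled to the median of each array the median change was 0.045, and rises made up 61.1% of the changed probes in place of 43.8%. With tumour 2 and tumour 4 averaged, 5670 probes were higher and 7241 lower in oogenesis. Averaging controls 2 and 3 and controls 4 and 5 as well left 10617 changed probes. Without controls 4 and 5, 11005 probes changed, and with slide as a fixed block 10245. Within slide 3, with 2 arrays of each group, 14571 changed. Slide 1 held 1 array of each of these groups, so their spread could not be estimated within it. Of the 14565 probes called within slide 3 and measured on slide 1, 92% had the same direction between oogenesis 1 and control 1, against 80.3% of all 31110 probes.

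**Figure D3:**
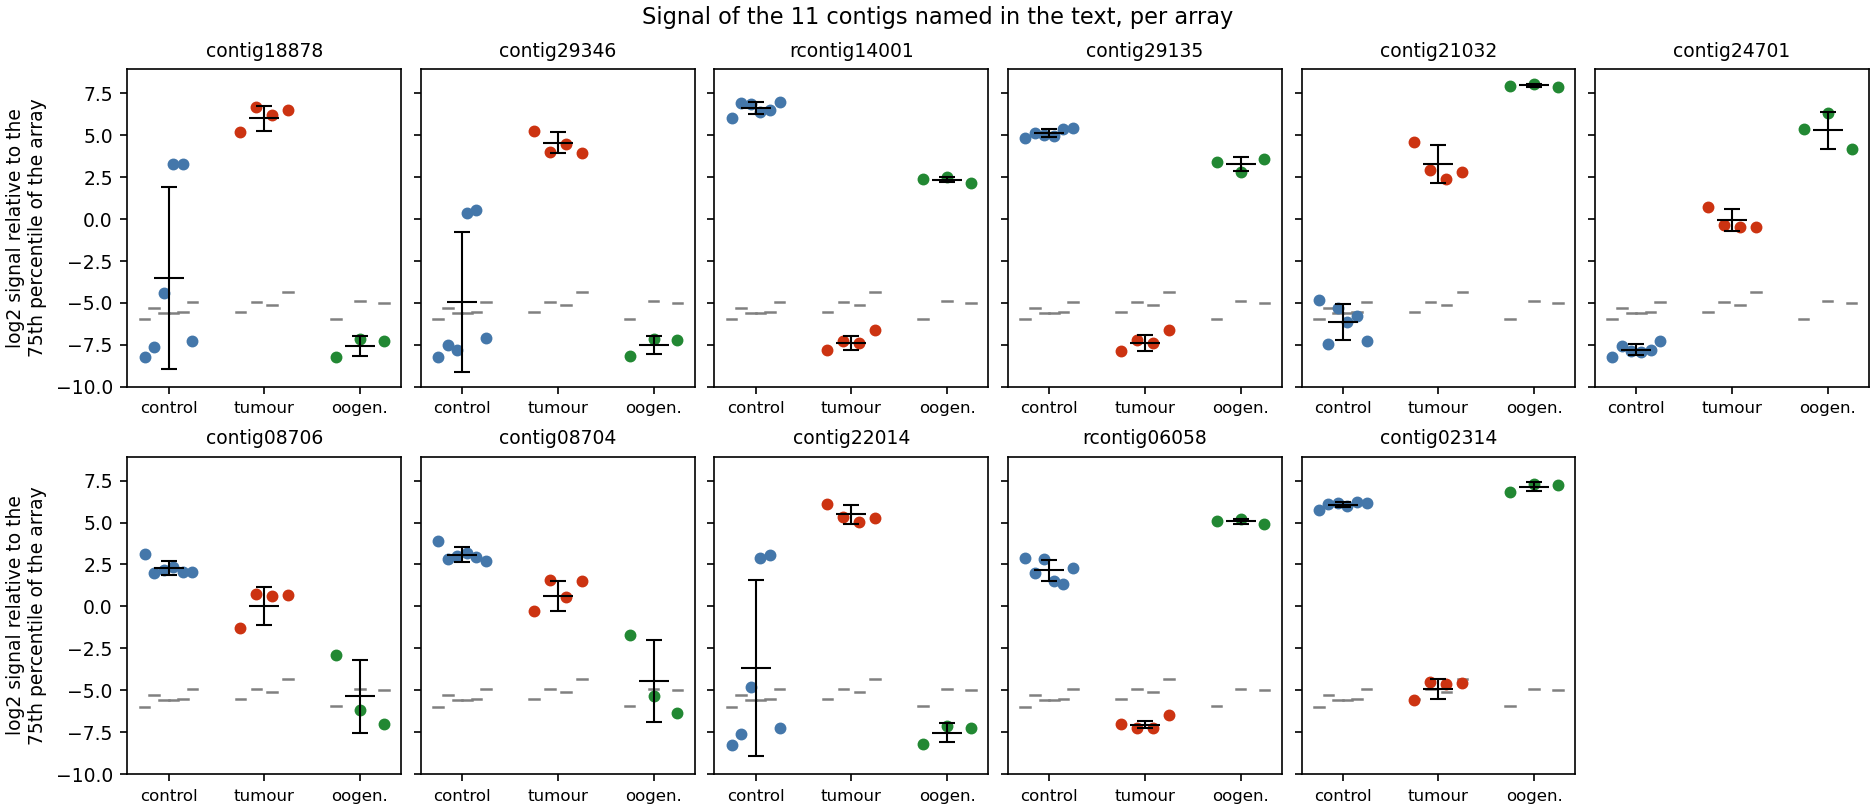
Log2 signal relative to the 75th percentile of the array for the 11 named contigs, with 1 point per array in control (blue), tumour (red) and oogenesis polyps (green); black bars give the mean ± SD, with tumour 2 and 4 counted once, and grey ticks the lowest signal well above background on each array. Contig18878, contig29346 and contig22014 show controls 4 and 5 far above the other controls.

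Tumour-bearing polyps were set directly against oogenesis polyps to see where the 2 states differ. Here 8514 probes were higher and 6590 lower in tumour polyps. With the median of each array as the scale, rises made up 41.3% of the changed probes in place of 56.4%, and the median log2 change of all probes was -0.14 in place of 0.142. The largest fitted rises were in contigs not well above background on any oogenesis array. Contig18878 was at least 2490-fold higher in tumour polyps than in oogenesis, where it stood at -7.55 ± 0.6. Its log2 change was 13.71 (SE 2.63, limma adjusted p = 0.0011, or 0.0034 with tumours 2 and 4 averaged). Contig22014, with the probe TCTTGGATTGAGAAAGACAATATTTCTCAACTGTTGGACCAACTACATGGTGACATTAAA, stood at 5.49 ± 0.56 in tumour and -7.53 ± 0.58 in oogenesis polyps and was at least 1740-fold higher (log2 change 12.98, SE 2.55, adjusted p = 0.0013). Its control mean was -3.67 ± 5.27, with 2.88 and 3.05 in controls 4 and 5. The SEs and p-values of contig18878 and contig22014 pool the spread within all 3 groups. The uneven controls thus enter them, although no control is compared here. Averaging tumours 2 and 4 gave contig22014 a limma adjusted p of 0.0036 against oogenesis.

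The largest fitted falls from oogenesis to tumour polyps were in transcripts that control polyps carried as well. Contig rcontig06058, with the probe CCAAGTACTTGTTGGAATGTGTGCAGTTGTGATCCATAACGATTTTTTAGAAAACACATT, stood at 5.07 ± 0.15 in oogenesis, 2.15 ± 0.64 in control and -7.06 ± 0.2 in tumour polyps, at least 1150-fold lower in tumour than in oogenesis (log2 change -12.09, SE 0.36, adjusted p = 2.1e-10). Contig02314, with the probe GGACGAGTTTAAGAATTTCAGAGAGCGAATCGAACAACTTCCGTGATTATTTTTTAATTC, stood at 7.12 ± 0.27 in oogenesis, 6.07 ± 0.16 in control and -4.92 ± 0.6 in tumour polyps, where 2 of the 4 arrays had it well above background (log2 change -11.95, or -11.98 with the other 2 at their detection limits and tumours 2 and 4 as 1 sample, SE 0.25, adjusted p = 2.5e-11). With tumour 2 and tumour 4 as 1 sample, the tumour and oogenesis samples did not overlap in 52.4% of the tested probes, where chance separates 10%. With tumour 2 and tumour 4 averaged, 6937 probes were higher and 5909 lower. Without controls 4 and 5, 13895 probes changed, and with slide as a fixed block 8929. Within slide 1, with 2 tumour arrays and 1 oogenesis array, limma called 0 and 3425 had an unadjusted p under 0.05.

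Tumour and oogenesis polyps shared part of their difference from asexual polyps. Against control, 1755 probes were higher in both and 2547 lower in both, while 1012 changed in opposite directions. The averaged fit gave 1477 higher and 2164 lower in both. Independent lists of these lengths would share 754 higher and 1225 lower probes, and 1922 would be opposite. Both comparisons use the same control arrays. With the controls split so that each comparison had 3 of its own, 1078 to 1386 probes were higher in both and 1471 to 1951 lower in both over 20 splits. The log2 changes correlated across probes, which are not independent replicates, with r = 0.33, inside the range that 100 simulations of unchanged groups gave (-0.43 to 0.8, 5th to 95th percentile). Their covariance was 0.519, above the simulated 0.038 (-0.044 to 0.153), and 0.334 to 0.583 with split controls. With slide as a fixed block 2807 probes were shared in one direction, against 4302 without. Averaging tumours 2 and 4, controls 2 and 3 and controls 4 and 5 left 2362 shared in one direction.

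Tumour polyps also stood apart from both other groups. Against control and oogenesis alike, 1988 probes were higher in tumour polyps and 2444 lower, and 1414 and 2129 with tumour 2 and tumour 4 averaged. Oogenesis polyps stood apart in more probes, with 4042 higher and 4692 lower than in both other groups, and 3684 and 4306 after averaging. A set of 441 probes on 431 contig names was well above background on every control and every oogenesis array and not on any tumour array. Their median level was -2.24 in control and -2.69 in oogenesis polyps, and the tumour level was lower by a median log2 value of at least 2.85 than in control. The opposite set, on in every tumour array and in no control or oogenesis array, held 19 probes, and 71 without controls 4 and 5, against 446 for the first set without them. A further 20 probes were on in every tumour and every oogenesis array and in no control array, with a median level of -3.19 in tumour and -0.53 in oogenesis polyps. Only in oogenesis arrays, on all 3 of them, 60 probes were well above background. Most tested probes, 22204, were well above background on all 13 arrays.

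**Figure D4:**
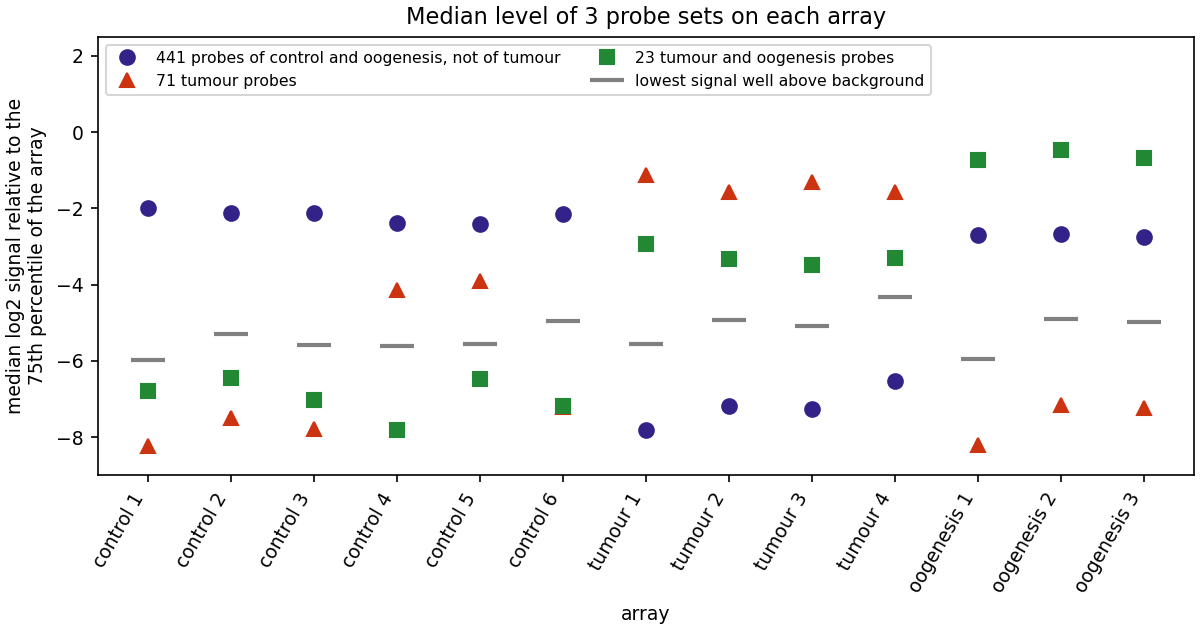
Median log2 signal relative to the 75th percentile on each array for the 441 probes of control and oogenesis polyps that are not above background in tumours (circles), 71 tumour probes (triangles) and 23 tumour and oogenesis probes (squares), the last 2 sets chosen without controls 4 and 5; grey ticks mark the lowest signal well above background. The 71 tumour probes stand at -4.15 and -3.91 in controls 4 and 5 and at -7.2 or below in the other controls.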

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

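All tests in this part were chosen after the pattern they concern was seen.

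Among 28 sets of values checked for a sample far from the rest of its group, 4 had one, where chance alone gives about 1 in 20. Contig08706 stood at 3.1 in control 1, with the nearest control at 2.38. The other 3 concern tumour 1. It had 0.72 for contig24701, with the nearest tumour array at -0.35. For contig08706 it had -1.27, with the nearest at 0.65, and for contig02314 it had -5.61, with the nearest at -4.6. As tumour 2 and tumour 4 are nearly equal, the tumour arrays are fewer than 4 unrelated samples. The check counted these arrays as separate values, so the rate of 1 in 20 does not hold for tumour sets. The 3 flags therefore cannot show that tumour 1 is apart.

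In tumour polyps, 441 probes that every control and oogenesis array carried were not well above background. With tumour 2 and tumour 4 as 1 sample, chance is argued against. Of the 84 splits of the tumour and control samples only 1, the real one, gave as many, and the highest other gave 32. Position on the slide was tested on the 670 probes on in every control and in no tumour array, a set chosen without the oogenesis arrays. Of these, 65.8% were on in both oogenesis 2 and 3, which lay at positions 3 and 4 like the tumours. Position is thus argued against as the cause for most of the 670. The probes on in both are the same 441, which were themselves chosen as on in every oogenesis array, so their signal there is no further test. Position stays open for the 167 of the 670 on in neither oogenesis 2 nor oogenesis 3, and for those on in only 1. Oogenesis 1, at position 1, had 594 of the 670 on. Its detection limit was also lower, at -5.95 against -4.9 and -4.99 in oogenesis 2 and 3. Position and detection limit cannot be told apart there. A lower signal of the tumour arrays is argued against for the 327 brighter of the 441 probes, since 96.1% of the 21158 probes in that range of control levels were well above background on every tumour array. For the 114 dimmer probes it stays open, since only 65.2% of 2885 probes in their range were. Sequence variants under the probes also stay open, because 0 tested probes of another sequence lie on the same contigs. Probes for the other orientation exist for 57, of which 25 were on in every tumour array and 19 in none. Loss of these transcripts with the tumour was not tested apart from other differences between the polyps, and the labels do not record descent within the strain.

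Controls 4 and 5 carried transcripts otherwise seen in tumour polyps. Of the probes on in every tumour array, in no oogenesis array and in exactly 2 controls, 45 were on in these 2, and any other pair of controls had at most 12. The slide and the scan are argued against. Controls 4 and 5 were on different slides and scan days, and of 76 such probes chosen without controls 4, 5 and 6, control 5 had 51 on. Control 6, on the same slide as control 5, had 5.88% of these 51 on, and control 4 had 92.2% (controls 5 and 6 compared by an exact two-sided binomial test, p = 2.3e-12, over probes, which are not independent). Tumour RNA mixed into the controls would bring probes that tumour and oogenesis polyps share. Of 14 such probes bright enough to be seen, 7.14% were on in both arrays. Of 29 tumour probes of like expected level, 75.9% were (exact two-sided Fisher p = 3.4e-05). The expected levels rest on a share estimated from the tumour probes themselves, so these were mostly on by construction. The probes are also not independent, so the p-value cannot decide the kind of RNA. A candidate explanation is polyps of a second kind in these 2 samples, with part of the tumour samples' profile but without tumour expression. The tumour probes imply a share of 11.6% in control 4 and slightly less in control 5. Such a share would dilute the 441 probes missing in tumours by a log2 value of -0.17. The observed shift was -0.18, outside the -0.03 to 0.05 of the other controls. Tumour RNA at the same share, which lacks these probes, would give the same shift. The shift therefore goes with an admixture but cannot tell its kind, on which only the low share of the 14 shared probes bears.

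Tumour 2 and tumour 4 were nearly equal. One scan deposited under both names is argued against, since 0 of their values are identical and they differed by 0.097 over the brighter probes. One RNA on both arrays is consistent with the weak recurrence of their difference in second probes of the same sequence (r = 0.22, against at least 0.87 in every other pair). The labels give no group in which to look for a biological explanation, and none was tested.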

How the results depend on the processing

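Alternatives chosen after the data were seen are the averaging of close arrays, leaving out controls 4 and 5, normexp on the median signal and one probe per sequence. The planned normexp correction with local background was not run, because 5 of the 13 files lack mean and background signals, and the gene lists had no names to test. The value table and the median over spots left every call as it was, so they test nothing and are not counted below. The 12 named results kept their direction and an adjusted p under 0.05 in all 212 values computed, the highest p being 0.017. Counts stayed within 1.5 times of 9261 for tumour against control in 23 of 30 alternatives, of 13120 for oogenesis against control in 26 of 29, of 15104 for tumour against oogenesis in 22 of 26 and of 4302 for probes shared in direction in 20 of 26. Leaving out 1 array at a time gave 7448 to 11609, 9879 to 12991, 11567 to 16669 and 3535 to 4749 in that order.

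For tumour against control, the count was 5433 with a log2 change of at least 1, 5654 at an adjusted p under 0.01, 2036 within slide 4 and 5276 with tumour 2 and 4, controls 2 and 3 and controls 4 and 5 averaged. Without controls 4 and 5 it was 6972. Oogenesis against control gave 8425 with a log2 change of at least 1. Tumour against oogenesis gave 9668 at an adjusted p under 0.01 and 8929 with slide as a fixed block. Probes shared in direction fell to 2807 with slide as a block, 2191 with a log2 change of at least 1, 2279 at an adjusted p under 0.01, 2801 with split controls and 2362 with the 3 close pairs averaged. Slide 1 alone gave 0 by limma in each of its 3 comparisons, with 2717, 2888 and 3425 at an unadjusted p under 0.05, but its 1 residual degree of freedom is the difference between tumours 1 and 2, so these counts say nothing about the other groups. Array weights raised the counts to 21604 for tumour against control and 23213 for tumour against oogenesis, where tumour 2 and tumour 4 took weights of 4.24 and 5.48 against 0.139 and 0.186 for tumours 1 and 3. Apart from stricter thresholds and fewer arrays, the cause was not tested.

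Samples of different groups share replicate numbers. Deviations of same-numbered samples correlated between -0.58 and 0.18 over 10 pairs, which gives no sign of pairing. Without differently numbered pairs beside them, these values cannot exclude it. With the replicate number as a block, 5308 probes changed between tumour and control, 8670 between oogenesis and control, 10169 between tumour and oogenesis, and 2169 in both in one direction. Signal over background limits what can be seen at low levels: detection limits ranged over 1.64 log2 units between arrays.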

Other observations

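All tests in this part were chosen after the values were seen.

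Both orientations of a contig were tested for 2667 contigs. Where both probes changed they mostly moved together: 287 of 313 in tumour against control, 493 of 511 in oogenesis against control and 772 of 835 in tumour against oogenesis. The opposite moves, 26, 18 and 63, are few, and the log2 changes of the 2 orientations correlated across contigs with r = 0.49, 0.67 and 0.51. The files do not say which orientation is the transcribed one.

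Tumour samples were the most uneven group, with a median SD per probe of 0.48 (3 values), against 0.353 in control and 0.185 in oogenesis polyps. One direction held 38.6% of the spread within groups. Tumour 1 stood at 0.6 on it, with controls 2 and 3 at 0.25 and 0.21, and tumour 2 and tumour 4 at -0.35 each, with control 1 at -0.48. Tumour 1, tumour 2 and control 1 share a slide and lie at both ends. Across probes its loadings hardly followed the change in tumour (r = -0.15) or oogenesis polyps (r = 0.14).

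Other splits of the samples, with tumour 2 and tumour 4 as 1 sample, were fitted over 31068 probes without missing values. For tumour against control the real split gave 7460 changed probes. It was the only 1 of 84 to reach that, the lowest share these splits can give, which argues against chance. The highest other gave 6085. It exchanged tumour 1 and control 1, which share slide 1 and lie at opposite ends of the direction above. The next split gave 1294. For oogenesis against control the real split gave 12884 and was the only 1 of 84, the highest other giving 7. This too is the lowest share these splits can give, and it argues against chance. Both sets of splits count the close controls 2 and 3, and controls 4 and 5, as separate samples. For tumour against oogenesis the 10 splits are too few for a share under 0.05, the real one, the only 1 to reach its count, giving 12827 and the highest other 0. With every array as a sample, the highest other split of that comparison put tumour 1 with the oogenesis arrays and gave 12527, against 15075 for the real one.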
